A study of Homo sapiens with 9 samples.

How the data were processed

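RNA was measured in 22Rv1, an established human prostate cancer cell line, carrying a stable fusion of dCasRx and METTL3. dCasRx is a catalytically dead CRISPR protein that a guide RNA directs to a chosen transcript, and METTL3 is the enzyme that writes N6-methyladenosine (m6A) on RNA. Per the labels' protocols, cells received a guide by lentivirus and were selected with 10 μg/mL blasticidin, total RNA was purified on RNeasy columns, and polyA RNA was sequenced on a NovaSeq instrument as paired reads of 150 bp. The 3 groups, with 3 libraries each, held a non-targeting guide, guide 1 or guide 2, both of the latter directed to the CHD9 transcript. Group and replicate number came from the sample labels. The series also describes a pooled screen of guides, which is not analysed here, and neither guide sequences nor m6A levels were used here.

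The deposited table holds raw read counts per gene, whole numbers with a different total in each library, that the authors had neither scaled nor filtered as far as the values show. Per the submitters' processing notes, Trim Galore, STAR and DESeq2 were used with the genome build hg38, with no versions. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand therefore cannot be told apart, and values of genes with near-identical copies, such as ribosomal protein and mitochondrially encoded genes, are uncertain to that extent. The number of columns with per-sample values that were not used was 0, and 0 reads lay on features that are not Ensembl genes.

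The table listed 67071 gene IDs, of which 60415 matched a table of symbols by ID, 58541 matched GENCODE release 29 and 6367 matched neither. Genes without a symbol kept their ID. Coordinates are 1-based positions from GENCODE release 29 on hg38, and the release the authors counted with may be another. No read was seen in any library for 30577 of the IDs. Total counts ran from 35543482 in guide 2 replicate 2 to 45964948 in guide 1 replicate 2. The common biological coefficient of variation of the fitted model was 1.82%. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

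Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test on TMM-normalized counts, after edgeR's default filter on low counts by group, which left 18394 genes. A single model over the 9 libraries with a mean per group gave 4 comparisons, guide 1 against non-targeting, guide 2 against non-targeting, the mean of both guides against non-targeting, and guide 2 against guide 1. Adjusted p is after Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Levels of single genes are CPM, counts scaled to a common library total with the TMM factors, computed here from the deposited counts. Exact permutation tests of CHD9 and METTL3 were two-sided and used the CPM of each library, and 3 against 3 libraries cannot give a p below 0.1.

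Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Camera asks whether a list ranks above or below the other genes. The fry test, used as an alternative, asks whether the genes of a list moved, without comparing them with the other genes. Lists are said to pass or not by camera unless another test is named. Of 38 lists, 36 had enough genes. The lists, the comparisons, the tests and the rule for naming genes were set before the data were examined. The rule took CHD9 and METTL3 always. It took the 10 genes with the largest increase and the 10 with the largest decrease for both guides together, and 8 of each for the other comparisons, among protein-coding genes past the threshold with a mean of at least 2 CPM and no overlap between the libraries compared. It also took the 3 members with the smallest adjusted p, in the direction of the list, from each list past the threshold. METTL14, MKI67, RBL2, AKTIP, FTO, CHD8 and TNC were named outside this rule, after seeing the data, as were the genes of the closing parts where this is said. Some genes that the rule took are not reported here.

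Alternatives set beforehand were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter at 1 CPM in at least 3 libraries, only the groups compared in the fit, the replicate number as a block, leaving out each library in turn, a threshold of 0.01, a fold change of at least 1.5, camera with an estimated correlation, and fry. Scaling by library size only, removal of mitochondrial genes, thinning to equal depth, removal of a trend on GC content per library, and the same removal with each library's median correction set to 0 were chosen after seeing the data. The last of these was added because the first GC removal shifted the median log2 fold change of all genes by -0.10 for both guides. GC content was known for 97.5% of the tested genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

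The tests were tried on simulated counts for the same 18394 genes and library sizes, with 200 genes changed in random directions. In the data far more genes were called, 71.8% for both guides, so the shares below need not hold there. For both guides against non-targeting, edgeR recovered 30% of the genes changed 1.1-fold, 66% at 1.25-fold, 84% at 1.5-fold and 86% at 2-fold, and called 0.0989% of the unchanged genes. For guide 1 against non-targeting the recovered shares were 26%, 64%, 84% and 86%, and for guide 2 they were 28%, 58%, 86% and 86%. For guide 2 against guide 1 they were 28%, 58%, 86% and 84%. Pairs of libraries of the same group differed by more than sampling noise. The chi-square per degree of freedom was 1.25 to 1.84 with the non-targeting guide and guide 1 and 2.48 to 6.06 with guide 2. This does not tell separate cultures from separate preparations of the same RNA. The model shares a single spread estimate per gene over all groups, so p-values of comparisons with guide 2 may understate its spread.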

Results

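Gene expression was measured in 9 libraries of 22Rv1 prostate cancer cells that stably express dCasRx-METTL3. The purpose stated by the labels was to install m6A on the mRNA of CHD9, a chromodomain helicase DNA-binding protein of the chromatin remodeler class, by guides directed to it. The comparisons therefore ask what each guide, or both together, changed against a non-targeting guide, and whether the guides differed. The first principal component of log2 CPM held 72.9% of the variance and ran from -56.6 to -55.1 in the non-targeting libraries, from 20.3 to 21.1 with guide 1 and from 34.5 to 35.4 with guide 2. The second held 5.64% and separated guide 2 from guide 1. Counts on the mitochondrial chromosome took 8.46% to 8.75% of the non-targeting libraries, 9.59% to 9.86% of the guide 1 libraries and 9.82% to 11.2% of the guide 2 libraries.

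CHD9 mRNA was slightly lower with both guides. CHD9 (ENSG00000177200.17) is a protein-coding gene at chromosome 16, 53055033 to 53329150, on the plus strand of hg38. It stood at 65.9 ± 1.59 CPM (SD, n = 3) with the non-targeting guide, 58.7 ± 0.657 with guide 1 and 58.2 ± 3.56 with guide 2. The log2 fold change was -0.17 with guide 1 (SE 0.0334, edgeR adjusted p = 7.6e-05), -0.18 with guide 2 (SE 0.0339, adjusted p = 2.7e-05) and -0.17 with both guides together (SE 0.0289, adjusted p = 4.8e-06), a level 11.4% lower. The exact permutation p was 0.1 for each guide, the smallest that 3 against 3 libraries allow, and 0.0119 for both guides, the smallest that 6 against 3 allow. Guide 2 over guide 1 gave -0.01 (95% confidence interval -0.08 to 0.06, adjusted p = 0.817), so no difference between the guides was detected. This decrease of CHD9 was smaller than the median absolute change of all tested genes, 0.29 for both guides, and 12284 genes (66.8%) changed by more. CHD9 has a GC content of 38.4%, below the lower quartile of 42.0% among tested genes. With a GC trend removed and the library level kept, a setting chosen after seeing the data, its change was -0.09 with guide 1 (adjusted p = 0.0165), -0.08 with guide 2 (adjusted p = 0.0243) and -0.08 with both (adjusted p = 0.00692), within a range of -0.21 to -0.08 for both guides over all alternatives.

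METTL3, the m6A writer that is also part of the fusion, was about 2-fold higher in both guide groups than in the non-targeting group. The gene (ENSG00000165819.12, chromosome 14, 21498133 to 21511375, minus strand) stood at 366 ± 5.24 CPM (SD, n = 3) with the non-targeting guide, 725 ± 4.51 with guide 1 and 785 ± 11.6 with guide 2. Its log2 fold change was 0.99 with guide 1 (SE 0.0181, adjusted p = 5.8e-26), 1.10 with guide 2 (SE 0.0182, adjusted p = 3.7e-27) and 1.04 with both. The exact permutation p was 0.1 for each guide and 0.0119 for both. Its partner METTL14 fell by 0.20 on the log2 scale with both guides (adjusted p = 1.6e-07). The table does not separate reads of the endogenous gene from reads of the fusion, and the end of METTL3 overlaps that of TOX4 on the other strand.

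**Figure D1:**
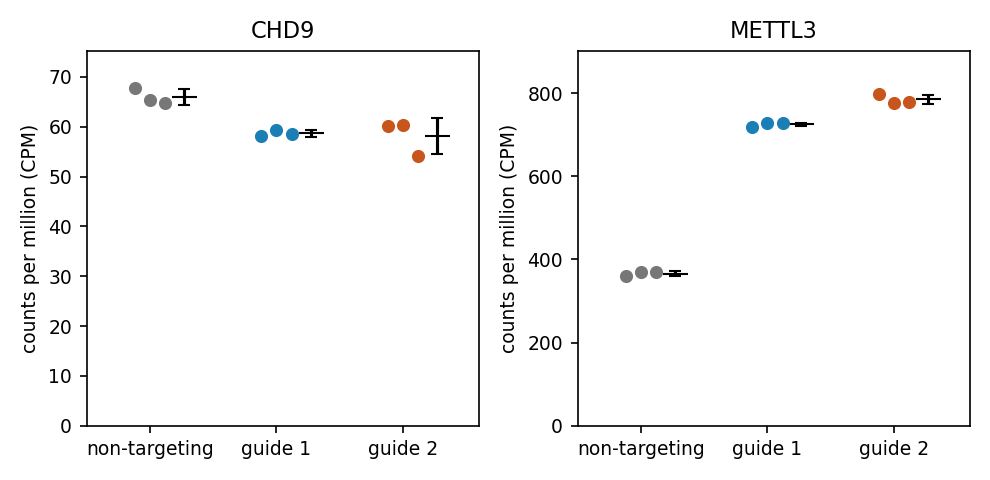
CHD9 (left) and METTL3 (right) in CPM (y axis, from 0) for the non-targeting, guide 1 and guide 2 groups (x axis), with 1 point per library and the mean with its SD beside them. CHD9 means were 65.9, 58.7 and 58.2 CPM, and METTL3 means were 366, 725 and 785 CPM.

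Near CHD9 the changes went both ways. Of the 7 tested genes fixed as its neighbours, 1 rose and 3 fell with both guides, and the same numbers were called when adjusted over the list alone. RBL2, a pocket protein of the retinoblastoma family 3' of CHD9, rose by 0.26 and AKTIP fell by 0.26, although these genes overlap at their ends. FTO, an m6A demethylase, was at 0.00 (95% confidence interval -0.03 to 0.04). The neighbours as a list did not pass (camera adjusted p = 0.543), with a median of -0.03 that ranged down to -0.26 over the 7 scaling settings. Of the 9 tested genes in the list of CHD family remodelers 5 rose and 3 fell, with CHD8 at -0.01 (adjusted p = 0.649). The list did not pass (adjusted p = 0.616). Its median was 0.06 and turned negative with a GC trend removed. Of 22 m6A writers, erasers and readers, 4 rose and 12 fell, and the list did not pass (adjusted p = 0.887), with a mean of 0.00 and a median of -0.06 that ranged down to -0.19 over the scaling settings.

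Most of the genes tested differed between both guides together and the non-targeting guide. In this comparison 6696 genes rose and 6504 fell, 71.8% of the 18394 tested, most of them by little, since 2920 rose and 1316 fell by at least 1.5-fold. TMM takes most genes as unchanged, which so many calls put in doubt. The near-even split and the sign of small changes therefore hold only relative to that scaling. With scaling by library size only, 6160 genes rose and 7148 fell, 46.3% of calls higher. Among genes that the rule for naming genes allows, the largest increases were those of NOVA2, a neuronal splicing regulator, and CNTN1, a neuronal cell adhesion protein. NOVA2 rose by 4.05 on the log2 scale (SE 0.158, from 0.284 ± 0.0386 CPM to 4.19 ± 0.389 with guide 1 and 5.33 ± 0.501 with guide 2, SD, n = 3) and CNTN1 by 3.84 (SE 0.0906). GLI1, the transcription factor of Hedgehog signalling, rose by 3.83 and MAFA, a transcription factor of pancreatic beta cells, by 3.71. FAM131B rose by 3.41, the sodium channel subunit SCN4B by 3.29, the complement component C3 by 3.29, the growth factor GDF7 by 3.15, the glutamate transporter SLC1A7 by 3.04 and the platelet receptor PEAR1 by 2.98. Several of these started near the floor. With the non-targeting guide the means were 0.202 CPM for GLI1, 0.300 for MAFA, 0.704 for SCN4B, 0.825 for C3, 0.860 for FAM131B and 0.865 for CNTN1. The bound of 2 CPM is a mean over all libraries, so such genes met it through the guide groups. The largest decrease by the same rule was that of the protocadherin PCDH17, at -2.45 (SE 0.116, from 5.17 ± 0.496 CPM to 1.07 ± 0.233 and 0.838 ± 0.144). POSTN, the matrix protein periostin, was at -2.31 (SE 0.0517), SYNPO2 at -2.12, RGS1, a regulator of G protein signalling, at -2.09, the growth factor IGF1 at -1.92, the plasma protein APOH at -1.91, the potassium channel KCNJ8 at -1.89, PLP2 at -1.79, the cadherin CDH2 at -1.66 and the glutamate receptor GRM3 at -1.66. By the rule used, the 6 guide libraries did not overlap the 3 non-targeting libraries for any of these genes. With the GC trend removed the split was 5258 higher and 8398 lower, 38.5% of calls higher against 50.7%, while the median of all genes shifted by -0.10, and with the library level kept it was 6750 and 6540.

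Genes of DNA replication and cell division were lower with both guides. None of the 38 tested G1/S genes rose and 37 fell (median -0.63, camera adjusted p = 3.7e-48). UHRF1, which maintains DNA methylation through replication, was at -1.06 (SE 0.0223), the replication licensing factor CDC6 at -0.86 and the replicative helicase subunit MCM4 at -0.65. Of 53 G2/M genes 4 rose and 46 fell (median -0.23, adjusted p = 1.9e-09), with the mitotic kinesin KIF20B at -1.15, cyclin A (CCNA2) at -0.45 and survivin (BIRC5) at -0.42. The proliferation marker MKI67 fell by 0.35. Of 31 MYC targets 1 rose and 29 fell (median -0.37, adjusted p = 7.5e-14), with the nucleolar proteins NCL at -0.53, NOLC1 at -0.45 and MRTO4 at -0.58. Cholesterol synthesis genes moved the same way, with 1 of 25 higher and 21 lower (median -0.44, adjusted p = 1.9e-11), among them HMGCS1 at -0.81, ACAT2 at -1.21 and IDI1 at -0.66. These 4 lists also passed with an estimated correlation.

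Targets of p53, immediate early genes, epithelial-mesenchymal transition genes and luminal markers were higher with both guides. Of 29 p53 targets 20 rose and 5 fell (median 0.32, adjusted p = 6.2e-07). The cell cycle inhibitor CDKN1A rose by 1.59 (SE 0.0227, from 70.1 ± 1.55 CPM to 201 ± 1.70 and 223 ± 7.48), ZMAT3 by 0.84 and TP53INP1 by 0.72. Of 25 immediate early genes 24 rose and 1 fell (median 0.98, adjusted p = 5.0e-15), with JUND at 1.01, EGR1 at 0.85 and KLF4 at 1.51. Of 18 genes of epithelial-mesenchymal transition 15 rose and 2 fell (median 0.88, adjusted p = 5.7e-05), with the hyaluronan receptor CD44 at 1.91, fibronectin (FN1) at 1.38 and the integrin ITGA5 at 1.66. The 2 that fell were the mesenchymal cadherin CDH2 and the matrix protein TNC, the latter named after its value was seen. Of the luminal epithelial markers 11 of 16 rose and 3 fell (median 0.29, adjusted p = 8.6e-06), with CLDN3 at 1.46, KRT8 at 0.68 and HOXB13 at 0.83. These 4 lists passed with an estimated correlation as well, at 0.0293 to 0.0337 for p53 targets, epithelial-mesenchymal transition genes and luminal markers.

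Other lists passed only with the preset correlation. Of 8 tested basal epithelial markers 7 rose (median 1.38), among them NGFR at 2.79, CAV1 at 1.58 and ITGB4 at 1.51 (adjusted p = 0.012, and adjusted p = 0.248 with an estimated correlation). Of 10 osteogenic genes 7 rose (median 0.87), with RUNX2 at 2.08 and COL1A1 at 1.25 (adjusted p = 0.00998, and adjusted p = 0.0738 with an estimated correlation). Of 14 Hippo pathway targets 11 rose and 1 fell (median 0.38), with AMOTL2 at 1.28, AMOTL1 at 0.70 and LATS2 at 0.48 (adjusted p = 0.0089, and adjusted p = 0.0738 with an estimated correlation). Of 23 hypoxia genes 13 rose and 6 fell (median 0.30), with CA12 at 0.94, VEGFA at 0.88 and P4HA1 at 0.92 (adjusted p = 0.00022, and adjusted p = 0.0588 with an estimated correlation). Of 22 PPAR alpha targets and fatty acid oxidation genes 13 rose and 8 fell (median 0.18), led by PDK4, a kinase that restrains pyruvate oxidation, at 2.01 (SE 0.0177), and SLC25A20 at 0.79 (adjusted p = 0.00042, and adjusted p = 0.142 with an estimated correlation). Of 74 cytosolic ribosomal protein genes 69 rose and 1 fell (median 0.32), with RPL15 at 0.62, RPL5 at 0.50 and RPL4 at 0.43 (adjusted p = 2.9e-21, and adjusted p = 0.0588 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose and 1 fell (median 0.25), with MT-CO1 at 0.35 and MT-ND5 at 0.49 (adjusted p = 0.018, and adjusted p = 0.657 with an estimated correlation). The share of all counts on the mitochondrial chromosome was 8.46% to 8.75% with the non-targeting guide and 9.59% to 11.2% with the others.

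Lists that were lower in this way included the nuclear-encoded subunits of oxidative phosphorylation. Of 58 such genes 4 rose and 47 fell (median -0.21), with ATP5MC1 at -0.55 and NDUFS5 at -0.29 (adjusted p = 2.3e-05, and adjusted p = 0.355 with an estimated correlation). Of 23 other chromatin remodelers 1 rose and 18 fell (median -0.15), with HELLS at -0.64, ARID2 at -0.42 and BPTF at -0.35 (adjusted p = 0.00257, and adjusted p = 0.173 with an estimated correlation). Of 19 nonsense-mediated decay factors and targets 5 rose and 13 fell (median -0.20), with the splicing factors SRSF2 at -0.61 and SRSF3 at -0.35 and the kinase SMG1 at -0.53 (adjusted p = 0.015, and adjusted p = 0.0738 with an estimated correlation). Of 27 Polycomb and Trithorax genes 7 rose and 16 fell (median -0.14), with CBX8 at -0.73 and RBBP4 at -0.31 (adjusted p = 0.044, and adjusted p = 0.112 with an estimated correlation). This last call also ended without non-targeting replicate 3 (0.0513), guide 1 replicate 1 (0.0504) or guide 2 replicate 1 (0.0509) and with a filter at 1 CPM (0.0704). Adjusted over the list alone, the counts of the lists above were the same, except for 12 higher Hippo targets and 9 lower PPAR alpha genes. Over the scaling settings, 7 or, for mitochondrially encoded genes, 6, the median of some lists moved by over 1.5-fold, down to 0.13 for luminal markers, 0.19 for p53 targets, 0.20 for ribosomal proteins, 0.15 for mitochondrially encoded genes, 0.11 for PPAR alpha genes, -0.29 for other remodelers and -0.23 for Polycomb and Trithorax genes, with no change of sign.

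**Figure D2:**
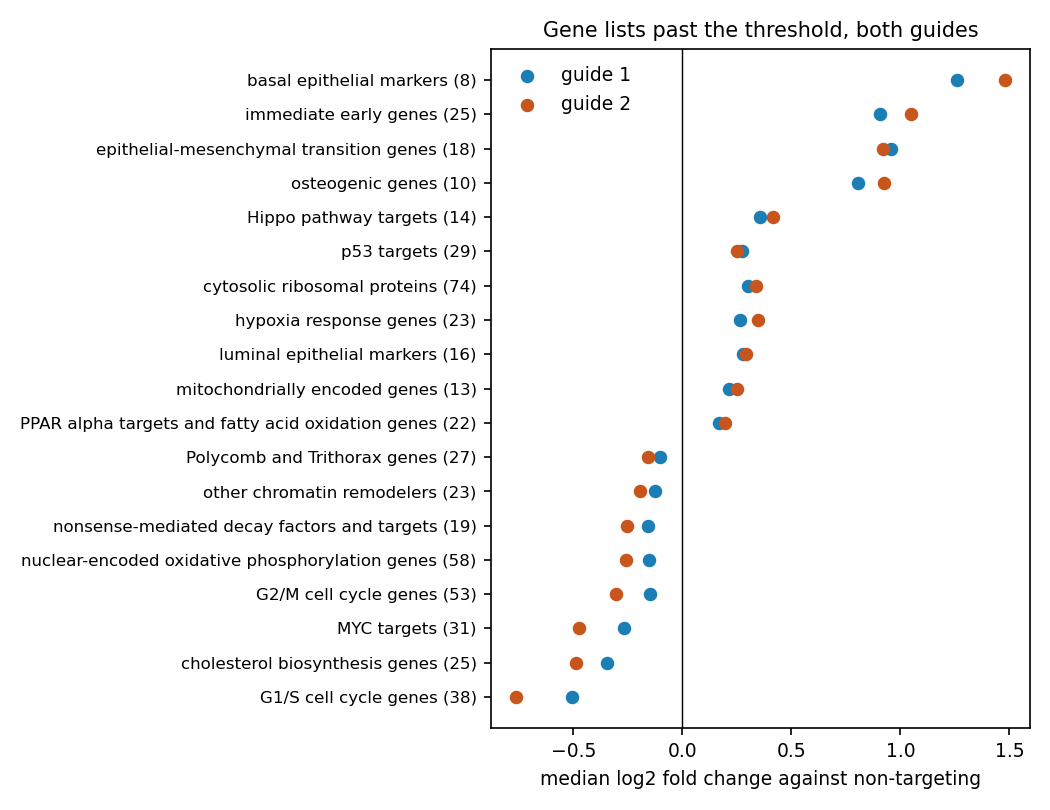
Median log2 fold change against the non-targeting group (x axis) of the 19 gene lists past the threshold for both guides (y axis, tested genes in brackets), with 1 point for guide 1 and 1 for guide 2. Both points of each list lie on the same side of 0, from -0.51 and -0.76 for G1/S genes to 1.26 and 1.48 for basal epithelial markers.

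Androgen-induced genes did not move in a common direction. Of 32 tested, 15 rose and 16 fell (median -0.02, mean 0.05, adjusted p = 0.827), and the median turned positive with the GC trend removed and the library level kept. Neuroendocrine prostate markers (6 higher, 6 lower of 17, median 0.03, mean 0.14, camera direction down, adjusted p = 0.827) did not pass, and their median turned negative with scaling by library size only or with the GC trend removed. Interferon-stimulated genes (18 higher, 8 lower of 29, median 0.46, adjusted p = 0.217) and NF-kB response genes (9 higher, 4 lower of 13, median 0.50, adjusted p = 0.329) did not pass as lists. Over the 7 scaling settings the interferon median went down to 0.24 and the NF-kB median to 0.20. Nor did fibroblast and stromal markers (8 higher, 1 lower of 9, median 0.77, adjusted p = 0.151) or replication-dependent histone genes (9 higher, 1 lower of 17, median 0.44, down to 0.21 over the scaling settings, adjusted p = 0.0619). Fatty acid synthesis genes (5 higher, 8 lower of 16, median -0.16, mean -0.03, adjusted p = 0.471) and glycolysis enzymes (4 higher, 8 lower of 18, median -0.07, down to -0.18 over the scaling settings, adjusted p = 0.302) did not pass. Stress lists did not pass either, with 15 higher and 9 lower of 27 ATF4 genes (adjusted p = 0.752), 7 and 10 of 22 ER unfolded protein response genes (adjusted p = 0.631) and 6 and 6 of 16 heat shock genes (median -0.02, mean 0.17, adjusted p = 0.937). The same held for 10 higher and 8 lower of 25 apoptosis regulators (adjusted p = 0.272), 5 and 4 of 14 WNT targets (adjusted p = 0.411) and 11 and 4 of 24 autophagy and lysosome genes (adjusted p = 0.272). The medians of these last 6 lists changed sign under at least 1 GC setting. Adjusted over the list alone, the counts that differed were 8 higher histone genes, 7 lower heat shock genes and 10 higher autophagy genes. With fry the androgen and neuroendocrine lists did not pass (fry adjusted p = 0.602 and 0.376), while the other lists above did. Among these, interferon (fry adjusted p = 8.1e-06) and NF-kB genes (3.5e-05) passed upward and fatty acid synthesis (0.0029) and glycolysis genes (0.0164) downward. Of 16 immune cell markers 3 were tested, of which 2 rose, and 0 of 10 endothelial markers passed the filter on low counts.

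With guide 1 alone 6072 genes rose and 5800 fell against the non-targeting guide, 64.5% of those tested. NOVA2 rose by 3.88, MAFA by 3.63, GLI1 by 3.54, CNTN1 by 3.49, FAM131B by 3.35, SCN4B by 3.14, C3 by 3.05 and TRPA1, an irritant-sensing cation channel, by 3.06 (SE 0.152). PCDH17 was at -2.28, SYNPO2 at -2.15, POSTN at -2.07, RGS1 at -1.97, KCNJ8 at -1.84, IGF1 at -1.83, APOH at -1.65 and PLP2 at -1.61. G1/S genes had a median of -0.51 (0 higher, 37 lower of 38, adjusted p = 2.0e-38), with UHRF1 at -0.87 and CDC6 at -0.71, and the G2/M kinetochore gene CENPF was at -0.35. The early response gene FOS rose by 1.55, the tight junction gene CLDN4 by 1.53, CD44 by 1.75, CDKN1A by 1.52, the Hippo target CCN1 by 0.99 and PDK4 by 1.83. In all, 11 lists passed upward and 8 downward, 19 that also passed for both guides together, and 6 and 4 of these passed with an estimated correlation. Adjusted over the list alone, the counts that differed among these lists were 12 higher luminal markers, 42 lower G2/M genes and 5 higher oxidative phosphorylation genes. With a filter at 1 CPM the mitochondrially encoded genes no longer passed (adjusted p = 0.0624). Hypoxia genes (adjusted p = 0.0383 with an estimated correlation) and ribosomal proteins (adjusted p = 0.0488 with an estimated correlation) passed that test here and not for both guides together. The groups of 3 libraries did not overlap for 68.9% of genes, where chance gives 10%. With the GC trend removed 4758 genes were higher and 7877 lower, at a median shift of -0.10, and with the library level kept 6245 and 5881.

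With guide 2 alone 6657 genes rose and 6361 fell against the non-targeting guide, 70.8% of those tested. NOVA2 rose by 4.22, CNTN1 by 4.19, GLI1 by 4.13, MAFA by 3.80, C3 by 3.53, FAM131B by 3.47, SCN4B by 3.44 and GDF7 by 3.36. PCDH17 was at -2.62, POSTN at -2.56, RGS1 at -2.22, APOH at -2.16, SYNPO2 at -2.08, PLP2 at -1.96 and KCNJ8 at -1.94, and IGF1 was also among the 8 largest decreases by the rule for naming genes. Adjusted over the list alone, 48 G2/M genes were lower instead of 47, the only such difference among the lists that passed. All 38 G1/S genes fell (median -0.76, adjusted p = 7.7e-51), with UHRF1 at -1.25 and the helicase subunit MCM5 at -1.13. The respiratory chain subunit COX5B was at -0.41 and the remodeler subunit BRD9 at -0.44. The early response gene KLF6 rose by 1.15, CDKN1A by 1.67, CD44 by 2.07 and PDK4 by 2.20. Here 11 lists passed upward and 7 downward, of which 4 and 4 passed with an estimated correlation, and Polycomb and Trithorax genes did not pass (adjusted p = 0.0725), although the test of the list between the guides gave an adjusted p of 0.873. The groups of 3 libraries did not overlap for 71.7% of genes, where chance gives 10%. With the GC trend removed 5292 genes were higher and 8117 lower, at a median shift of -0.11, and with the library level kept 6675 and 6448.

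Called genes overlapped widely between the guides. In both comparisons 5667 genes rose and 5256 fell, where independent calls would share 2198 and 2006, numbers that ignore the shared controls. Simulated unchanged groups against the same controls shared 0.05 and 0.25 on average. Few unchanged genes are called in either comparison, so these simulated counts had to lie near 0 and do not gauge the overlap. Across genes, which are not independent replicates, the log2 fold changes of the guides had a correlation of 0.947, against 0.483 in the simulations, and a covariance of 0.430 against 0.0185, a difference of 0.411. The simulations shared the same controls, so the modelled spread between single control libraries is already in the 0.0185. A difference that all 3 non-targeting libraries have in common was not simulated, and part of the excess may come from it. Separate controls for each guide were not tried, since 3 libraries cannot be split into parts of at least 2 each. Opposite calls were made for 17 genes.

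**Figure D3:**
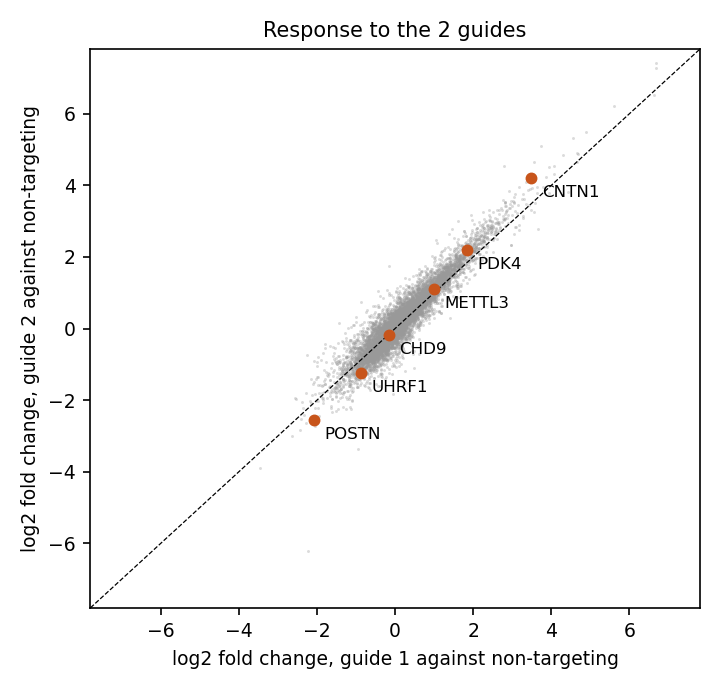
Log2 fold change against the non-targeting group with guide 1 (x axis) and guide 2 (y axis), with 1 point per tested gene, 6 named genes in orange and a dashed line where both are equal. The 18394 genes lie along a diagonal with a correlation of 0.947, with CHD9 at -0.17 and -0.18 and CNTN1 at 3.49 and 4.19.

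Between the guides, cell cycle genes and MYC targets were lower with guide 2 than with guide 1. None of the 38 G1/S genes was higher and 37 were lower (median -0.24, adjusted p = 1.5e-52), with MCM5 at -0.42 (SE 0.0276), MCM4 at -0.28 and MCM7 at -0.28. Of 53 G2/M genes 43 were lower (median -0.13, adjusted p = 1.3e-19), with CCNB1 at -0.24, BIRC5 at -0.23 and CCNA2 at -0.18. Of 31 MYC targets 27 were lower (median -0.21, adjusted p = 3.3e-28), with NCL at -0.24, NOLC1 at -0.21 and ODC1 at -0.20. These 3 lists passed with an estimated correlation as well. In all, 2283 genes were higher and 2738 lower with guide 2, 27.3% of those tested, and 227 and 39 by at least 1.5-fold. With the GC trend removed 2024 were higher and 3375 lower, with the library level kept 2263 and 2996, and with DESeq2 1533 and 2251. The groups of 3 libraries did not overlap for 38.7% of genes, where chance gives 10%.

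Lower with guide 2 at the preset correlation were also nuclear-encoded oxidative phosphorylation genes (2 higher, 40 lower of 58, median -0.11), with ATP5MC1 at -0.28, ATP5MC3 at -0.21 and ATP5PB at -0.14 (adjusted p = 3.4e-12, and adjusted p = 0.232 with an estimated correlation). Of 25 cholesterol synthesis genes 16 were lower (median -0.12), with DHCR7 at -0.26 (adjusted p = 1.9e-06, and adjusted p = 0.163 with an estimated correlation). Of 22 ER unfolded protein response genes 3 were higher and 14 lower (median -0.11), with the chaperones HSPA5 at -0.18, PDIA4 at -0.21 and HSP90B1 at -0.13 (adjusted p = 1.3e-05, and adjusted p = 0.143 with an estimated correlation). Of 18 glycolysis enzymes 2 were higher and 9 lower (median -0.10), with PGAM1 at -0.27 and ENO1 at -0.20 (adjusted p = 0.00018, and adjusted p = 0.327 with an estimated correlation). Of 16 heat shock genes 1 was higher and 8 were lower (median -0.05), with FKBP4 at -0.16 (adjusted p = 0.027, and adjusted p = 0.244 with an estimated correlation). That call ended with a filter at 1 CPM (adjusted p = 0.0740).

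Higher with guide 2 were immediate early genes (10 higher, 5 lower of 25, median 0.15), with ZFP36 at 0.38 and KLF6 at 0.31 (adjusted p = 0.028, and adjusted p = 0.163 with an estimated correlation). That call ended with either GC trend removal (0.101 and 0.0831). Of 29 p53 targets 13 were higher and 4 lower (median 0.08), with GADD45A at 0.33, BTG2, which the early gene list also holds, at 0.18 and CDKN1A at 0.15 (adjusted p = 0.033, and adjusted p = 0.266 with an estimated correlation). Of 74 ribosomal protein genes 25 were higher (median 0.0277, down to 0.0142 over the scaling settings), with RPL28 at 0.14 (adjusted p = 0.0015, and adjusted p = 0.448 with an estimated correlation). Without guide 2 replicate 3 the p53 list (0.0777) and the ribosomal list (0.0521) no longer passed. Adjusted over the list alone, the counts became 38 lower G1/S genes, 47 lower G2/M genes, 3 higher and 44 lower oxidative phosphorylation genes, 3 and 12 glycolysis genes, 2 and 10 heat shock genes and 11 and 6 early genes, with no change for the other lists that passed. Larger differences were called for genes outside the rule for naming genes, since 45 genes were higher by at least 2-fold and 15 lower. Among genes that the rule allows, the furthest apart were the unconventional myosin MYO15B at 0.78 (SE 0.0538), the calcium channel CACNA1I at 0.77, SEC31B at 0.73, P2RX2 at 0.72, ARRDC3 at 0.72 (SE 0.0252), DCST2 at 0.71, CNTN1 at 0.70 and PLEKHH2 at 0.70. On the other side, by the same rule, stood the amino acid transporter SLC6A19 at -0.73 (SE 0.171), AGR2 at -0.61, EBLN2 at -0.56, the apoptosis gene BID at -0.50, POSTN at -0.49, MRPL12 at -0.47, APOH at -0.51 and RMDN2 at -0.49. Without guide 1 replicate 1 APOH was at -0.33 (adjusted p = 0.113) and RMDN2 at -0.29 (adjusted p = 0.206), and RMDN2 was not called without guide 2 replicate 1 either, at -0.49.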

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

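The tests of other groupings and of the GC trend between the guides were set before their results were seen, and the other tests below were chosen only after the result was seen.

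The first pattern is METTL3, which was about 2-fold higher in both guide groups although the guides were directed to CHD9. Normalization and depth are argued against as the cause, since the lowest METTL3 log2 fold change for both guides over all settings was 0.99 and the highest 1.09. A gain of the chromosome region is argued against by the 12 tested genes within 500 kb of METTL3, which had a median log2 fold change of 0.0834 (quartiles -0.16 and 0.30). The neighbouring gene SALL2 did rise by 1.07, and a gain or a change of transcription limited to these genes was not tested. The table held 0 features for the construct, so reads from the dCasRx-METTL3 fusion and from the endogenous gene cannot be told apart, and a higher level of the fusion in the guide groups may be the source.

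The second pattern is the number of changed genes, 13200 for both guides together, in an experiment directed to 1 transcript whose own change was small. Of 100 regroupings of the 9 libraries, 1, the real grouping, gave as many, and the highest other gave 12165. The 2 others that kept the non-targeting libraries as the control group gave 12124 and 12165. Of the 97 that did not, the highest gave 8216 and 8037 and the next 55. These 97 may include groupings that kept the non-targeting libraries together under a guide label. The samples therefore have a structure that parts the non-targeting libraries from the rest. Spread between single libraries is argued against as its source. Libraries of a group may share a culture, however, so a chance difference between cultures is not excluded. A GC trend is argued against as the whole cause, since at least 88.5% of the calls stayed in the same direction under both GC removals and the G1/S median stayed at -0.61 or lower, and depth likewise, since 97.3% stayed at equal depth. An effect of guide-directed m6A on CHD9, a difference in the level of METTL3 and any other difference between the cultures cannot be told apart, since each would coincide with the groups, and each may contribute. That 0 non-targeting libraries had METTL3 within the range of the guide libraries restates the METTL3 difference and decides nothing.

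For the single comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. In fits on the 6 libraries concerned, 1 split of 10, the real one, gave as many genes in each, with 12122 called for guide 1 against a highest other of 0, 12680 for guide 2 against 0, and 4742 for guide 2 against guide 1 against a highest other of 1.

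The third pattern is that guide 2 differed from guide 1 mostly in the direction in which guide 1 differed from the non-targeting guide. Across genes the correlation of these differences was 0.243, while noise in the shared guide 1 libraries gave at most -0.470 in simulated unchanged groups and is argued against. With the GC trend removed the correlation was 0.235 or higher, against GC content as the cause, although the second GC setting was added after the first was seen. A single common scale for all genes is argued against, since 34 of 38 G1/S genes (median -0.19), 40 of 53 G2/M genes (-0.115) and 26 of 31 MYC targets (-0.173) were lower with guide 2 than a slope of 1.10 on guide 1 predicts, with oxidative phosphorylation (-0.0992) and glycolysis genes (-0.113) moving likewise, although epithelial-mesenchymal transition genes (-0.00348) and luminal markers (0.0139) lay near it. A stronger action of guide 2, through CHD9 or through the higher METTL3, may remain, and so may a difference between cultures. For CHD9 mRNA no difference between the guides was detected (-0.01, edgeR adjusted p = 0.817), and m6A levels were not used. METTL3 was higher with guide 2 by 0.11 (edgeR adjusted p = 1.5e-05).

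A test of the difference between the guides also set apart the medians of 11 gene lists. They were -0.24 for G1/S genes, -0.13 for G2/M genes, 0.0753 for p53 targets, -0.11 for ER unfolded protein response genes, -0.0483 for heat shock genes, 0.15 for immediate early genes, -0.10 for glycolysis enzymes, -0.12 for cholesterol synthesis genes, -0.21 for MYC targets, 0.0277 for cytosolic ribosomal proteins and -0.11 for nuclear-encoded oxidative phosphorylation genes. With an estimated correlation only 3 of these lists passed, G1/S, G2/M and MYC targets, and the p53, ribosomal, heat shock and immediate early calls also ended under other settings. The same test set apart METTL3 at 0.11, NOVA2 at 0.34, GLI1 at 0.59, CNTN1 at 0.70, SCN4B at 0.30, C3 at 0.48, GDF7 at 0.43, POSTN at -0.49, RGS1 at -0.25 and APOH at -0.51, which was at -0.33 and not called without guide 1 replicate 1.

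Genes past the threshold in opposite directions under the guides numbered 17. The difference between the guides passed for each of them, which choosing genes in this way nearly ensures, so it adds no further support. Chosen from these after their values were seen, HES1, a Notch target, was at -0.25 with guide 1 and 0.17 with guide 2. The endonuclease partner EME2 was at -0.13 and 0.42, the chaperone HSPA5 at 0.13 and -0.05, the cytokinesis factor ECT2 at 0.05 and -0.07, and EBLN2 at 0.29 and -0.26.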

How the results depend on the processing

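The settings on library size only, mitochondrial genes, thinning and GC content were chosen only after the results were seen, and the others were set before. Every alternative for CHD9 and METTL3, 158 in all, kept the direction and the side of the threshold, or, for CHD9 between the guides, stayed short of it. CHD9 for both guides ranged from -0.21 to -0.08 and METTL3 from 0.99 to 1.09. Leaving out 1 library, which leaves 2 in its group, gave -0.18 to -0.15 for CHD9 with guide 1 and -0.21 to -0.13 with guide 2. Of the counts of genes 207 stayed within 1.5 times and 11 did not. A fold of at least 1.5 was met by 2586 higher and 1112 lower genes with guide 1, 3209 and 1517 with guide 2, 2920 and 1316 with both, 227 and 39 between the guides, and 2449 and 866 called the same way with each guide, fewer because the criterion is stricter. A threshold of 0.01 left 1433 genes higher with guide 2 than with guide 1. Among named genes 5271 values stayed and 3 lost the call, those of APOH and RMDN2 given above. Among lists 2708 stayed, 49 lost the call, 38 of these with an estimated correlation, and 119 gained it, 53 with fry and 25 with no filter on low counts. No result changed its direction while called.

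Replicate numbers did not pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.020 to 0.014, others at -0.031 to 0.032, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block, 6069 genes were higher and 5798 lower with guide 1, 6645 and 6349 with guide 2, 6692 and 6503 with both, and 2274 and 2739 between the guides. Polycomb and Trithorax genes for both guides no longer passed (0.0546), and between the guides the epithelial-mesenchymal transition (0.0491), osteogenic (0.0469) and mitochondrially encoded genes (0.0445) did. Fits on only the groups compared gave no value for both guides or for lists, DESeq2 gave no list test, only list medians, and a pseudocount did not apply to counts. In simulated counts 26% to 30% of genes changed 1.1-fold were recovered.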

Other observations

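The families of genes below, the androgen and interferon genes and the check of small RNAs were chosen only after the data were seen, while the test of the methylation motif was set before its result was seen and the spread of its rank was added after.

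Besides the lists fixed beforehand, 19 families defined by gene name were tested for both guides with camera. Some families share genes with those lists, such as CLDN3, ITGA5 and COL1A1, and are not independent of them. Of 40 proteasome subunit genes 0 rose and 39 fell (median -0.26, adjusted p = 1.5e-07), with PSMC3 at -0.39. Of 73 mitochondrial ribosomal protein genes 6 rose and 59 fell (median -0.23, adjusted p = 9.0e-07), with MRPL37 at -0.50. All 10 Fanconi anaemia genes fell (median -0.39, adjusted p = 5.6e-05), with FANCB at -0.84. Of 10 replicative DNA polymerase genes 9 fell (median -0.51, adjusted p = 2.4e-06), with POLE at -0.70, and of 22 nuclear pore genes 19 fell (median -0.27, adjusted p = 9.0e-07), with NUP205 at -0.37. On the other side, 23 of 30 collagen genes rose and 1 fell (median 0.82, adjusted p = 1.0e-05), with COL12A1 at 2.46 and COL6A2 at 1.29, as did 17 of 23 integrin genes against 4 lower (median 0.66, adjusted p = 0.00079), with ITGA9 at 1.87, and 6 of 8 claudins (median 0.78, adjusted p = 1.2e-05), with CLDN4 at 1.58. These 8 families passed with an estimated correlation too, at 0.0422 or lower, and kept their direction under the 7 scaling settings. Ephrins and their receptors (14 higher, 2 lower of 20, adjusted p = 0.0014, and adjusted p = 0.102 with an estimated correlation) passed upward only with the preset correlation. Their median of 0.39 went down to 0.17 over the scaling settings. Aminoacyl-tRNA synthetases did so downward (3 higher, 24 lower of 32, adjusted p = 0.00061, and adjusted p = 0.117 with an estimated correlation). Chaperonin subunits did likewise (1 higher, 8 lower of 9, adjusted p = 0.0475, and adjusted p = 0.212 with an estimated correlation). Keratins passed upward in this way (4 higher, 0 lower of 5, adjusted p = 0.0111, and adjusted p = 0.201 with an estimated correlation). So did cyclin-dependent kinase inhibitors (4 higher, 4 lower of 8, adjusted p = 0.0274, and adjusted p = 0.127 with an estimated correlation). The median of this last family was 0.0990 and turned negative, at -0.0668, with the GC trend removed.

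The androgen-induced genes, which did not move as a list, held large changes both ways with both guides. KLK3, which encodes prostate-specific antigen, was at -0.97 (SE 0.0557, adjusted p = 4.4e-15), KLK2 at -0.56 and KLK4 at -0.62. TMPRSS2, a serine protease, was at 1.28 (SE 0.0302, adjusted p = 1.1e-23), STEAP2 at 1.07, ALDH1A3 at 1.67 and SLC45A3 at 1.19. Interferon-stimulated genes likewise parted, with IFIT1 at 3.17, OASL at 2.78, IFIT2 at 2.14 and BST2 at 1.63, against RSAD2 at -0.77, CMPK2 at -0.67 and DTX3L at -0.57. Among readers of m6A, IGF2BP2 was at 1.18 and YTHDC2 at -0.28, and among writers WTAP was at -0.27. CHD5 was at 0.87 and CHD1 at -0.32.

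Small nuclear RNAs had a median log2 fold change of -0.48 over 21 tested genes with both guides, 2 higher and 8 lower, and small nucleolar RNAs of -0.29 over 44, with 5 higher and 15 lower. Both medians stayed below 0 under the 7 scaling settings. These RNAs mostly lack a polyA tail, so their reads depend on the selection of polyA RNA. Chromosome medians for both guides ran from -0.12 on chromosome 21 to 0.08 on chromosome 3.

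A hypothesis tested was that the higher METTL3 acts on transcripts through its preferred motif GGACT. If so, the density of the motif in a gene's transcript should stand out from that of the 59 other orders of the same bases in its rank correlation with the fold change for both guides. GGACT ranked 56 of 60 from the lowest, with a rank correlation across genes of 0.0525 in a range of -0.0461 to 0.0710. The highest was TGGAC (0.0710), which shares the stretch GGAC with GGACT. Orders that overlap the motif may carry part of its effect, so they are not clean controls. The rank of GGACT lies within the bound set beforehand for no effect, the middle 90% of ranks. In 200 resamplings of the genes, however, 95% of the ranks ran from 46 to 58, past that bound, and 127 resamplings lay inside it, so a motif effect was neither excluded nor shown.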
